A study of Mus musculus with 6 samples.

How the data were processed

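Total RNA from 6 pooled samples of mouse extraembryonic ectoderm was measured on Affymetrix gene expression arrays, 3 arrays per genotype. Per the labels' protocols, the tissue was dissected at embryonic day 6.5, each pool held the tissue of about 20 to 25 embryos, RNA was extracted with Trizol, and 100 ng per pool was labelled with the Ambion WT kit. The labels describe the pools as separate biological replicates. Samples were grouped by the genotype in the submitters' labels, as Esrrb mutant or wild type, and replicate numbers came from the same label.

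The values used are the table of log2 signals that the authors deposited, 1 value per feature and array. The submitters' processing notes name affy 1.44.0. The steps of background correction, normalization and summarization are not given in the sources used here. The log base is not stated by a label. It was taken as 2 because the highest values, near 13.8, exceed the natural logarithm of the brightest signal a scanner of this kind records. Array medians lay between 6.10 and 6.11, so the arrays had been scaled to each other before deposit, and a change in the total amount of RNA per cell cannot be seen in such values. Signals were not centred per feature. The table has no detection calls, so background is unknown, and for some genes a low signal is described by its percentile among all features. The number of arrays, 3 per group, limits the precision of every difference. The precise genetic lesion is not given in the sources used here.

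Genes were named through the platform annotation supplied with the series. Of 34760 features, 21640 listed 1 gene, 1321 listed several and 11799 were unnamed here. Symbols were updated through the gene identifier against a gene table of assembly GRCm38.p6, in which 21553 of the 21640 features found a match. No coordinates are printed, since the array table names no genome build. The gene table served only for names, for the chromosome of a gene and for which genes neighbour each other. Features with several genes or none entered no gene-level test. Where a gene had more than 1 feature (954 genes), the feature with the highest mean over all 6 arrays was used, which left 19937 genes.

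The difference between genotypes, mutant minus wild type, was estimated on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate, 4 residual degrees of freedom per gene before moderation). Values of p were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every adjusted p in the text is from this two-sided limma test unless stated otherwise. Group values are the mean ± SD of 3 arrays. Before the data were examined, 28 gene lists were fixed (cell types, signalling pathways, metabolic and stress programs). Each was tested with limma's camera, which compares the members' differences with those of all other genes, with a preset inter-gene correlation of 0.01, and adjusted over the 28 lists. Camera with the correlation estimated from the data and limma's fry served as alternatives. When the correlation is estimated, camera also takes p from the 4 residual degrees of freedom, not from a number based on the genes tested. A call lost in that setting can therefore come from fewer degrees of freedom as well as from correlation. Adjustment over the members of a list alone is given beside the adjustment over all genes. The lists were drawn from general knowledge, not from these samples.

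The genes named in the text were chosen by a rule fixed before the data were examined. It takes Esrrb, the 15 called genes with the largest fall and the 15 with the largest rise, a set of 15 genes always named (of which Gcm1 had no feature of its own), and up to 4 members per list with the smallest p. Predicted genes and clone names were counted but skipped in the ranking (5 called genes). The rule names 136 genes, of which the text gives the most relevant. A few genes outside the rule are marked where they appear.

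The test was checked on simulated data made from the means and spread of these 6 arrays. With 50 genes changed at each size, the comparison of mutant with wild type over 19937 genes recovered 64% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. Of 185 calls, 6 were false. The genes of the extraembryonic ectoderm and trophoblast stem state list were lowered as well and counted as truly changed. Simulated genes were drawn independently of each other, whereas members of the real lists were correlated, by an estimated 0.42 for parietal endoderm. These rates may therefore not carry over to the real arrays.

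Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, leaving out dim genes (mean below the median of all features), eBayes with a trend or robust, array weights, the mean of a gene's features, every feature tested on its own, the replicate number as a block, each array left out in turn, a minimum difference of 1 log2 unit and an adjusted p under 0.1. Added after the data were seen were a score of decidual markers as a covariate and list tests without the called genes.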

Results

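Gene expression was measured in the extraembryonic ectoderm of embryonic day 6.5 mouse embryos, the trophoblast tissue that lies against the epiblast and harbours trophoblast stem cells. Embryos mutant for Esrrb, an orphan nuclear receptor of the estrogen-related receptor family, were compared with wild type. The series asks what Esrrb does in this tissue for the specification of primordial germ cells, the founders of the germ line, which arise in the neighbouring epiblast in response to signals from the extraembryonic ectoderm. There were 3 pools per genotype, each of about 20 to 25 embryos, and 1 array per pool. The 6 arrays had median log2 signals of 6.10 to 6.11. Pearson correlations over the 19937 genes tested (genes are not independent replicates) were 0.993 to 0.996 within the mutant, 0.996 to 0.997 within wild type and 0.991 to 0.995 between genotypes.

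Esrrb itself was lower on every mutant array. Its log2 signal was 6.19, 6.16 and 6.46 in the mutant pools and 8.07, 7.90 and 7.83 in the wild-type pools, a difference of -1.66 (SE 0.10, 3.16-fold, adjusted p = 2.03e-04). The mutant mean still lay at percentile 52.7 of all features. Whether the probes of this feature lie within the altered part of the gene is not given in the sources used here, so the remaining signal does not measure remaining function. The relatives Esrra and Esrrg, which encode the other receptors of the family, differed by 0.019 (SE 0.07) and -0.020 (SE 0.10), less than the spread between pools.

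Of 19937 genes, 151 passed the threshold, 81 lower and 70 higher in the mutant. Nr0b1, Elf5, Bmp4 and Msx1 were among the genes that fell, while Hand1, Afp, Trf, Postn and Dcn were among those that rose. The median called difference was -0.69 for the lower and 0.69 for the higher genes, and 22 lower and 12 higher genes differed by at least 1 log2 unit. At an unadjusted p under 0.05 there were 1120 lower and 1330 higher genes. The 2 groups of arrays did not overlap for all 151 called genes and for 18.7% of all genes tested, against 10% by chance. The number of calls was 47 without wild-type replicate 1, 47 without wild-type replicate 2 and 265 without mutant replicate 3. With a score of maternal decidual markers as a covariate, added after the data were seen, 11 genes passed, while the median difference went from 0.69 to 0.56 for the higher and from -0.69 to -0.65 for the lower genes, all 81 lower and 70 higher genes kept their sign, and the median standard error of the higher genes went from 0.10 to 0.16.

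**Figure D1:**
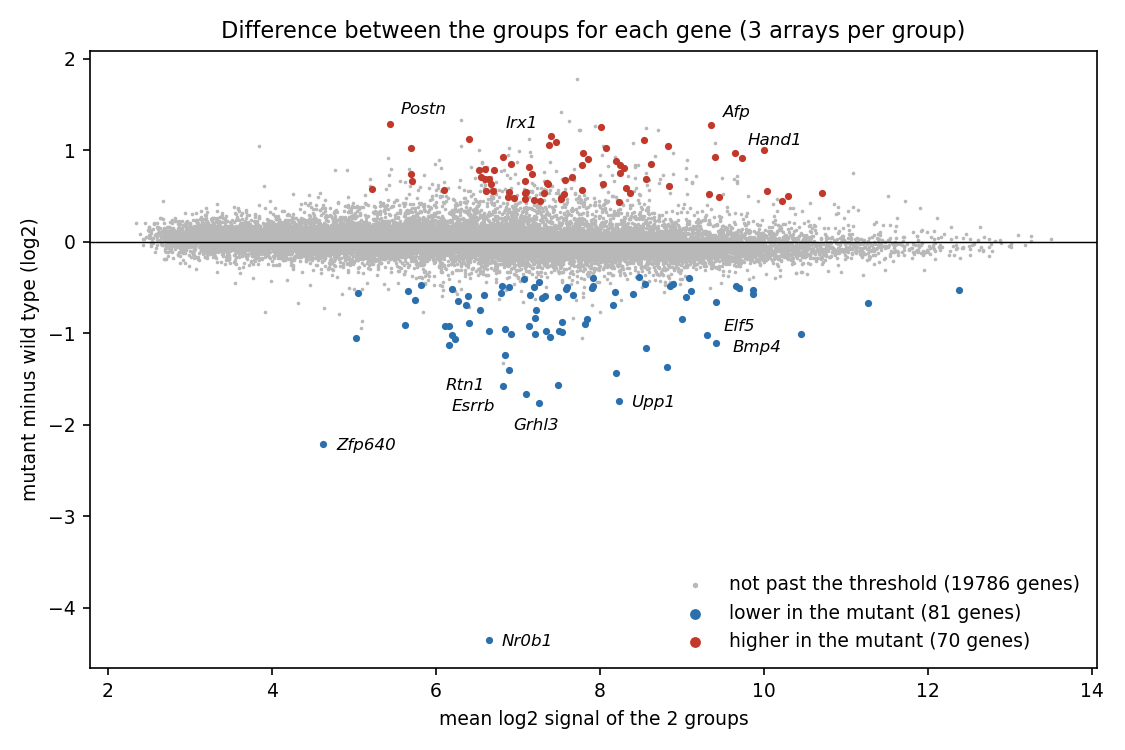
Each point is a gene, with its mean log2 signal over both genotypes on the horizontal axis and the log2 difference, mutant minus wild type, on the vertical axis (3 arrays per group). The 81 genes called lower and the 70 called higher are coloured, and Nr0b1 at -4.35 lies farthest from 0.

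Nr0b1, which encodes an orphan nuclear receptor and corepressor that is an Esrrb target in embryonic stem cells, fell by more than any other gene. Its log2 signal was 8.83 ± 0.14 (SD, n = 3) in wild type and 4.48 ± 0.61 (SD, n = 3) in the mutant, a difference of -4.35 (SE 0.25, 20.4-fold, adjusted p = 1.97e-04). The mutant mean lay at percentile 23.3 of features, where background is unknown. The epithelial transcription factor Grhl3 differed by -1.76, the uridine phosphorylase Upp1 by -1.74 and the reticulon Rtn1 by -1.57. Nat8l, the N-acetylaspartate synthase, differed by -1.40, the ephrin ligand Efna3 by -1.37, the inositol phosphatase Inpp1 by -1.24 and the diacylglycerol kinase Dgka by -1.16. Nexmif, the phosphatase 2A subunit Ppp2r2c and the single-stranded DNA binding factor Radx differed by -1.12, -1.06 and -1.05. Zfp640 differed by -2.21, but it belongs to a family of zinc finger genes with near-identical copies that these probes may not separate, so the identity of the transcript is uncertain. The mutant means of Zfp640 and Radx lay at percentiles 10.8 and 23.6 of features. The kinase gene Wnk3 differed by -1.43 (adjusted p = 0.0328) and lost its call without any array but mutant replicate 3 (highest adjusted p 0.166); the other genes of this paragraph kept theirs with any array left out.

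Among the genes with the largest rises, the matrix protein periostin, Postn, rose from 4.79 ± 0.15 to 6.08 ± 0.23 (SD, n = 3), a difference of 1.29 (SE 0.12, adjusted p = 0.00303). Its wild-type mean lay at percentile 28.1 of features. The serum protein gene Afp rose by 1.28, the pepsinogen Pga5 by 1.25, the Iroquois homeobox gene Irx1 by 1.16, the glycosyltransferase Gcnt4 by 1.09, the lysophosphatidylcholine transporter Mfsd2a by 1.02, the death ligand Fasl by 1.02 and the chondroitin synthase Chsy1 by 1.00. Nudt11 (1.13), the secreted protein Olfml3 (1.11), the kinase C substrate Marcks (1.06), the ion transport regulator Fxyd5 (1.05), Cmtm5 (0.97) and the huntingtin-associated protein Hap1 (0.93) also passed. Markers of maternal decidua were higher in the same mutant pools, with a median difference of 0.53. Postn, Afp, Irx1, Mfsd2a, Fasl and Chsy1 kept their calls with any array left out. Gcnt4 lost its call without wild-type replicate 1 (adjusted p 0.0572), Pga5 without wild-type replicate 1 or 2 (highest 0.0550), and Nudt11, Olfml3, Marcks, Fxyd5, Cmtm5 and Hap1 each without 3 to 5 of the arrays, wild-type replicate 2 among them (highest 0.159).

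Of 23 measured genes of the extraembryonic ectoderm and trophoblast stem state, 5 were lower, 0 higher and 18 did not pass. The list's median was -0.23 (quartiles -0.58 and -0.014, camera adjusted p = 3.07e-06), with an adjusted p = 0.317 with an estimated correlation and an adjusted p = 0.116 without the called genes. The 5 were Nr0b1, Bmp4, Sox21, Elf5 and Id2. Elf5, a transcription factor needed to form this tissue, went from 9.81 ± 0.041 to 8.80 ± 0.34 (SD, n = 3), a difference of -1.02 (SE 0.15, adjusted p = 0.0200). Sox21, a SoxB transcription factor, differed by -0.97 (SE 0.07, adjusted p = 6.27e-04) and the inhibitor of DNA binding Id2 by -0.67 (adjusted p = 0.0206). Other stem cell regulators did not pass: Sox2 differed by -1.05 (SE 0.21, adjusted p = 0.0674), Cdx2 by -0.49 (SE 0.11, adjusted p = 0.111), Eomes by -0.36 (SE 0.13, adjusted p = 0.288) and Tfap2c by -0.23 (SE 0.15, adjusted p = 0.602). Without mutant replicate 3, Sox2 (-1.32, adjusted p = 0.00109) and Eomes (-0.52, adjusted p = 0.0143) passed, and Tfap2c differed by -0.035. On that array Sox2 (7.79) was higher than in mutant replicates 1 and 2 (6.84 and 7.13). So was the epiblast gene Pou5f1, at 9.79 against 8.46 and 8.55. Adjusted over the list alone, 11 members were lower and 2 higher, which were Gata3 (0.73, adjusted p = 0.0813 over all genes, and 0.92 with adjusted p = 0.00280 without mutant replicate 3) and Tfap2a (0.40, adjusted p = 0.118), both chosen after their values were seen. Elf5 lost its call without mutant replicate 2 or any wild-type array and Id2 without mutant replicate 1 or any wild-type array (highest adjusted p 0.128 for both). Decidual markers were higher in these mutant pools, with a median of 0.53.

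**Figure D2:**
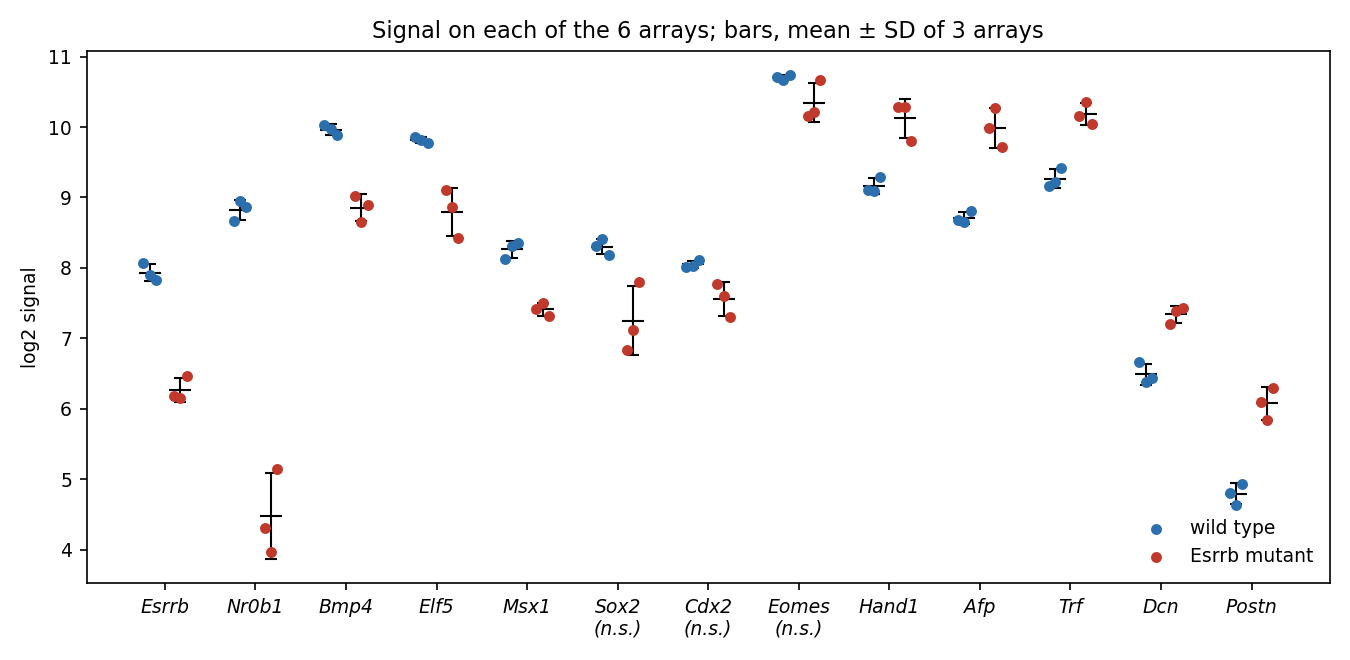
The log2 signal of 13 genes is shown for each of the 3 wild-type arrays (blue) and 3 mutant arrays (red), with bars for mean ± SD, and n.s. marks genes that did not pass the threshold. Bmp4 lay near 9.96 in wild type and 8.86 in the mutant, while Eomes, at 10.70 and 10.35, did not pass.

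Signals known to act on germ cell specification were examined next. Bmp4, the extraembryonic ectoderm ligand that induces primordial germ cells in the epiblast, fell from 9.96 ± 0.072 to 8.86 ± 0.19 (SD, n = 3), a difference of -1.11 (SE 0.10, 2.15-fold, adjusted p = 0.00261), and stayed past the threshold with any array left out. Pcsk6, a proprotein convertase that processes TGF-beta family ligands, differed by -0.55 (SE 0.08, adjusted p = 0.0213). Its call was lost without mutant replicate 2 or any wild-type array (highest adjusted p 0.138). Bmp8b, the other BMP ligand of this tissue with a role in germ cell induction, differed by -0.43 (SE 0.17, adjusted p = 0.347) and Bmp7 by -0.60 (SE 0.15, adjusted p = 0.129), neither past the threshold. Without mutant replicate 3 Bmp8b differed by -0.20. Of 15 measured genes in this list, 2 were lower, 0 higher and 13 did not pass, and adjusted over the list alone 3 were lower and 3 higher. The 3 higher were Bmp2 (0.84, adjusted p = 0.193), which is also in the decidual list, Nodal (0.56, adjusted p = 0.214), also in the epiblast list, and the BMP antagonist Nog (0.25, adjusted p = 0.190), the first 2 chosen after their values were seen. Without mutant replicate 3 Nodal differed by 0.35. The list as a whole had a median of -0.055 and did not pass (camera adjusted p = 0.278), with a median of -0.015 without wild-type replicate 2 and -0.027 without wild-type replicate 3.

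Of 21 measured BMP pathway and target genes, 5 were lower, 0 higher and 16 did not pass, and adjusted over the list alone 7 were lower and 0 higher. The list's median was -0.10 (camera adjusted p = 0.00152; adjusted p = 0.463 with an estimated correlation, and adjusted p = 0.736 without the called genes), and -0.038 without mutant replicate 3, where the list still passed. Decidual markers had a median of 0.53 in the same pools. The homeobox genes Msx1 and Msx2, which BMP signals induce, differed by -0.85 (SE 0.08, adjusted p = 0.00311) and -0.62 (SE 0.08, adjusted p = 0.0131). The BMP-induced inhibitor Smad6 differed by -0.57 (SE 0.08, adjusted p = 0.0131) and Id2 by -0.67. Smad7, a further inhibitory Smad chosen after its value was seen, differed by -0.46 (adjusted p = 0.0213). Msx1 kept its call with any array left out. Msx2 lost its call without mutant replicate 2 or wild-type replicate 2 (highest adjusted p 0.0955), Smad6 without any wild-type array (highest 0.0967), Id2 as above (0.128) and Smad7 without any array but mutant replicate 3 (highest 0.141).

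In the list of ectoplacental cone and spongiotrophoblast genes, 4 of 22 measured members rose, 1 fell and 17 did not pass. Hand1, a transcription factor that promotes trophoblast giant cell differentiation, went from 9.16 ± 0.11 to 10.13 ± 0.28 (SD, n = 3), a difference of 0.97 (SE 0.13, adjusted p = 0.0145). The growth factor receptor Egfr differed by 0.50 (adjusted p = 0.0193), the integrin Itga7 by 0.64 (adjusted p = 0.0225), and Rhox9, an X-linked homeobox gene chosen after its value was seen, by 0.52 (adjusted p = 0.0443). Phlda2, an imprinted gene that restrains placental growth, differed by -0.52 (adjusted p = 0.0303). Ascl2, a regulator of spongiotrophoblast, differed by 0.072 (SE 0.21), with the sign turned without mutant replicate 1 (-0.028) or 2 (-0.11) and 0.35 without mutant replicate 3. The spongiotrophoblast marker Tpbpa differed by -0.67 (SE 0.61, adjusted p = 0.725) and by 0.21 without wild-type replicate 3, the array where its signal was 6.42, or -1.23 without wild-type replicate 1. Its mutant and wild-type means lay at percentiles 16.5 and 25.9 of features. Adjusted over the list alone, 6 were higher and 2 lower. The list's median was 0.11, from 0.035 to 0.17 with 1 array left out (camera adjusted p = 0.0458; adjusted p = 0.593 with an estimated correlation), and the call was lost without any array but the third of either genotype (highest adjusted p 0.316) and under quantile normalization (0.0785). Without the called genes the list's adjusted p was 0.650. The median of decidual markers was 0.53 in the same pools. Hand1 and Egfr lost their calls without mutant replicate 2, wild-type replicate 1 or wild-type replicate 2 (highest adjusted p 0.105 and 0.128), Phlda2 without mutant replicate 2 or any wild-type array (highest 0.164), and Itga7 and Rhox9 without any array but mutant replicate 3 (highest 0.135 and 0.212).

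Neither giant cell genes (18 measured, 1 higher, which was Hand1; median 0.086, camera adjusted p = 0.278) nor genes of chorion and syncytiotrophoblast (17 measured, 0 called; median 0.014, from -0.011 to 0.064 with 1 array left out, camera adjusted p = 0.606) passed as lists. Without wild-type replicate 3 the giant cell list passed, with a median of 0.35 (camera adjusted p = 1.62e-04), and without wild-type replicate 1 its median was -0.11. Adjusted over the list alone, 1 giant cell gene was higher, and 3 chorion and syncytiotrophoblast genes were higher and 2 lower. The giant cell prolactin Prl2c5 differed by -0.72 (SE 0.41, adjusted p = 0.542), and by -0.15 without wild-type replicate 3, where its signal was 6.13, or -1.13 without wild-type replicate 1. Its mutant and wild-type means lay at percentiles 20.5 and 31.3 of features. In the chorion list, the receptor Fzd5 differed by 0.59 (SE 0.14, adjusted p = 0.119) and the ligand Wnt7b by -0.38 (SE 0.10, adjusted p = 0.171). FGF and ERK genes, which relay the FGF4 signal that keeps trophoblast stem cells dividing, did not pass as a list (20 measured, 0 called; 3 lower and 2 higher adjusted over the list alone; median -0.029, from -0.070 to -0.013 with 1 array left out, camera adjusted p = 0.306). Among them the ERK phosphatase Dusp6 differed by -0.37 (SE 0.08, adjusted p = 0.105) and the receptor Fgfr2 by -0.29 (SE 0.08, adjusted p = 0.193), while the cyclin Ccnd1, chosen after its value was seen, differed by 0.72 (adjusted p = 0.237), or 0.46 without mutant replicate 3.

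Markers of maternal decidua, the uterine tissue around the conceptus, rose as a list, with a median of 0.53 (quartiles 0.33 and 0.67, camera adjusted p = 7.43e-10; adjusted p = 0.317 with an estimated correlation). Of 19 measured, 17 had a higher mean in the mutant pools, but 1 was called higher, 1 called lower and 17 did not pass. The matrix proteoglycan Dcn differed by 0.85 (SE 0.10, adjusted p = 0.00592), and the secreted protease Htra1 by -0.90 (SE 0.09, adjusted p = 0.00311). The uterine homeobox gene Hoxa10 differed by 0.53 (SE 0.10, adjusted p = 0.0655) and the collagen Col1a1 by 0.57 (SE 0.11, adjusted p = 0.0628), which passed without mutant replicate 2 (adjusted p 0.0382) or 3 (adjusted p 0.0428). Adjusted over the list alone, 13 were higher and 1 lower. Parietal endoderm genes also rose as a list, with a median of 0.21 over 17 measured and 0 called (8 higher adjusted over the list alone; camera adjusted p = 1.05e-06, adjusted p = 0.463 with an estimated correlation). Of these, Stc1 differed by 0.64 (SE 0.15, adjusted p = 0.108; 0.45 and adjusted p = 0.0391 without mutant replicate 3) and the laminin Lamc1 by 0.44 (SE 0.11, adjusted p = 0.132). Blood and endothelial genes had a median of 0.10 over 18 measured, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0286; adjusted p = 0.463 with an estimated correlation). Their call was lost without mutant replicate 1, wild-type replicate 1 or wild-type replicate 2 (highest adjusted p 0.134) and under quantile normalization (0.0649). Without dim genes the members that remained had a median of 0.50, and the list passed (camera adjusted p = 0.00558). The endothelial cadherin Cdh5 differed by 0.97 (SE 0.27, adjusted p = 0.166), with 9.12 on the array of wild-type replicate 3, and passed without that array (1.34, adjusted p = 0.00875).

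Visceral endoderm genes rose as a list, with 2 of 29 measured called higher and 27 not passing. The list's median was 0.091 (quartiles 0.021 and 0.50, camera adjusted p = 1.03e-05; adjusted p = 0.463 with an estimated correlation), and adjusted over the list alone 10 were higher and 1 lower. Afp, the alpha-fetoprotein of visceral endoderm, went from 8.71 ± 0.086 to 9.99 ± 0.28 (SD, n = 3), a difference of 1.28 (SE 0.13, adjusted p = 0.00320). Transferrin, Trf, differed by 0.92 (SE 0.10, adjusted p = 0.00530). Apoa4 (0.50, adjusted p = 0.0734) and Apoa2 (1.22, adjusted p = 0.115) did not pass, although both did without mutant replicate 3 (0.61, adjusted p = 0.00845, and 1.63, adjusted p = 1.82e-04). Epiblast genes did not pass as a list (23 measured; median 0.16, camera adjusted p = 0.380). Their median was 0.028 without mutant replicate 3, 0.044 without wild-type replicate 1 and 0.31 without wild-type replicate 3. Adjusted over the list alone, 7 were higher and 4 lower. Dppa2 and Dppa4, paired nuclear factors of pluripotent cells, were lower, by -0.84 (SE 0.08, adjusted p = 0.00303) and -0.92 (SE 0.14, adjusted p = 0.0229), the latter not without mutant replicate 2 or any wild-type array (highest adjusted p 0.141). The epiblast genes Fgf5 and Pou5f1 differed by 1.22 (SE 0.32, adjusted p = 0.153) and 0.75 (SE 0.34, adjusted p = 0.431), with the highest signals, 9.17 and 9.79, on the array of mutant replicate 3, and Pou5f1 by 0.32 without it. Mesoderm genes did not pass as a list (24 measured; median 0.061, from 0.0073 to 0.13 with 1 array left out, camera adjusted p = 0.203). Of these, Postn and Hand1 were higher, Bmp4 and the T-box gene Tbx20 (-0.91, adjusted p = 0.00303) lower, and adjusted over the list alone 5 were higher and 2 lower.

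**Figure D3:**
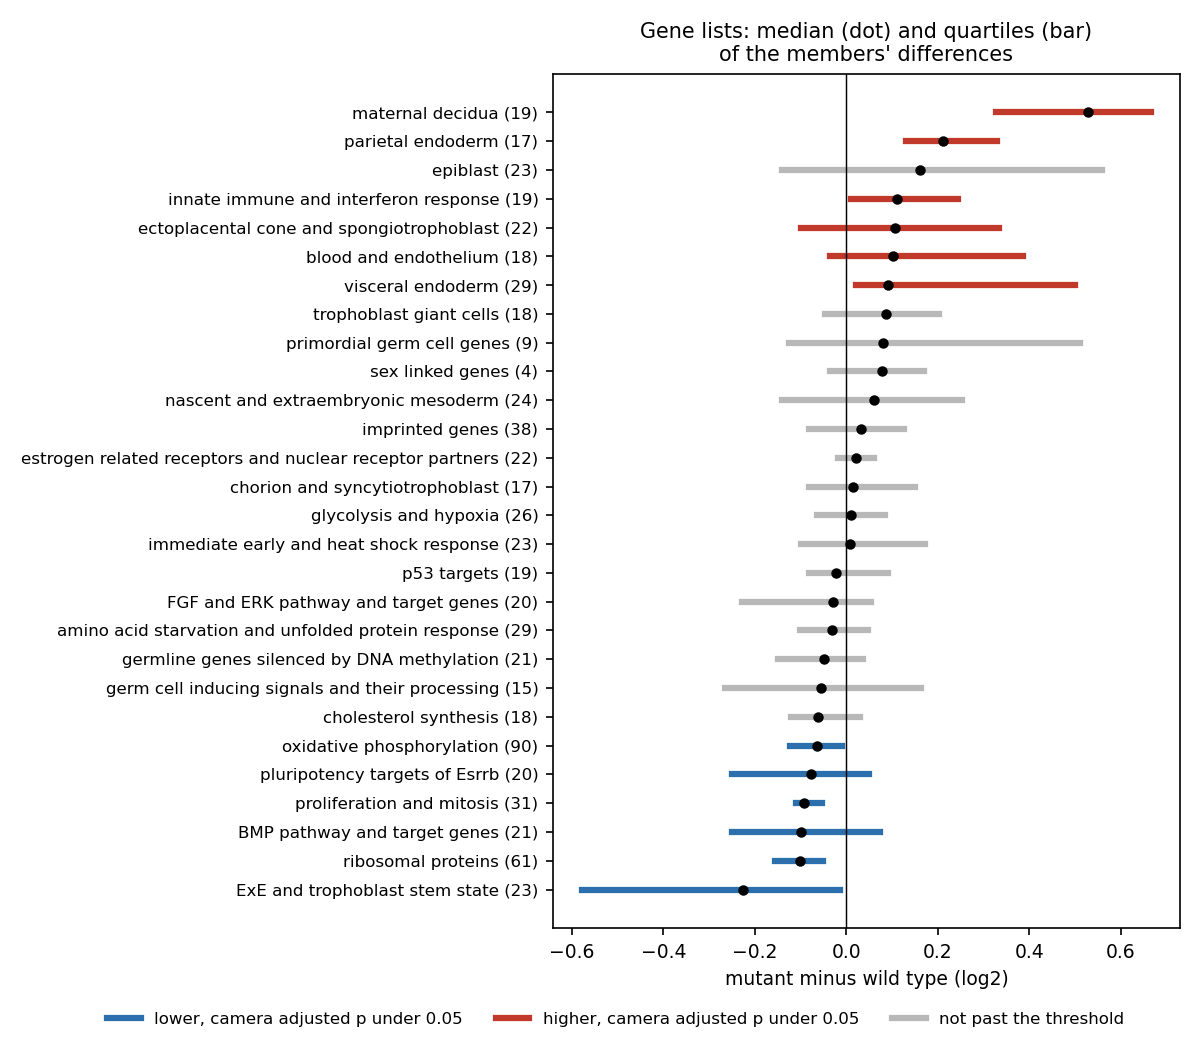
For each of the 28 gene lists, the dot is the median and the bar spans the quartiles of its members' log2 differences, mutant minus wild type, with the number of measured genes in parentheses. Coloured bars are the 12 lists past the threshold with the preset correlation, from the stem state list at -0.23 to maternal decidua at 0.53. With an estimated correlation, a setting that also rests on 4 degrees of freedom, 0 lists passed.

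Pluripotency genes that Esrrb binds in embryonic stem cells were lower as a list, with a median of -0.078 over 20 measured and 0 called (4 lower adjusted over the list alone; camera adjusted p = 0.0453, adjusted p = 0.427 with an estimated correlation). The estimated correlation, -0.0047, lay below the preset 0.01, so correlation among the members does not account for the call lost with it. That setting also rests on 4 degrees of freedom, which raises p. With the preset, the call was lost without either of mutant replicates 1 and 2 or of wild-type replicates 1 and 2 (highest adjusted p 0.140). It was also lost under quantile normalization (median -0.036, adjusted p 0.0927) and without dim genes, where the median was larger in size (-0.12, adjusted p 0.128). The list's members with the smallest p were Sox2, at -1.05, and Tfcp2l1, at -0.34 (SE 0.08, adjusted p = 0.105). In the same pools, decidual and parietal endoderm markers had medians of 0.53 and 0.21. Nuclear receptors and partners did not pass as a list (22 measured; camera adjusted p = 0.412). Nr0b1 was lower, and the estrogen receptor Esr1 was higher by 0.55 (SE 0.07, adjusted p = 0.0129), although not without wild-type replicate 1 or 2 (highest adjusted p 0.0892). The nuclear receptor Nr2f2 differed by 0.39 (adjusted p = 0.0612). That list had a median of 0.022, from 0.0061 to 0.045 with 1 array left out, and a mean of -0.13, and adjusted over the list alone 2 were lower and 2 higher. Primordial germ cell genes did not pass (9 measured, 0 called; 3 higher and 1 lower adjusted over the list alone; median 0.080, from -0.0014 to 0.14 with 1 array left out, camera adjusted p = 0.236). Prdm1 differed by 0.51 (SE 0.13, adjusted p = 0.156; 0.67 and adjusted p = 0.0372 without wild-type replicate 3), Prdm14 by -0.33 (SE 0.09, adjusted p = 0.156) and Kit by 0.55 (SE 0.15, adjusted p = 0.156). Germline genes silenced by DNA methylation did not pass either (21 measured; median -0.048, camera adjusted p = 0.203), except without wild-type replicate 3 (adjusted p 0.0433), and the median was -0.011 without mutant replicate 2. The helicase gene Mov10l1 was lower by -0.51 (SE 0.08, adjusted p = 0.0234), not without mutant replicates 1 or 2 or wild-type replicates 1 or 2 (highest adjusted p 0.127). Tex19.1 differed by -0.54 (SE 0.12, adjusted p = 0.101), and 2 members were lower when adjusted over the list alone. Imprinted genes showed 1 lower (Phlda2) and 1 higher (Dcn) of 38 measured, the same numbers adjusted over the list alone (median 0.032, from -0.0039 to 0.057 with 1 array left out, camera adjusted p = 0.380). The fetal growth factor Igf2 differed by -0.22 (SE 0.07, adjusted p = 0.248).

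Among lists for growth and metabolism, ribosomal protein genes had a median of -0.10, with 56 of 61 lower and 0 called (camera adjusted p = 3.07e-06; adjusted p = 0.511 with an estimated correlation). Proliferation genes had a median of -0.093, with 30 of 31 lower and 0 called (camera adjusted p = 1.76e-04; adjusted p = 0.511 with an estimated correlation), among them Mcm2 at -0.20 and Cdc20 at -0.23. Without mutant replicate 1 the proliferation list's median was -0.054 and its adjusted p 0.0766. Genes of oxidative phosphorylation had a median of -0.065, with 71 of 90 lower and 0 called (camera adjusted p = 0.00321; adjusted p = 0.534 with an estimated correlation), and Ndufaf2 at -0.33. That call was lost without mutant replicate 3 (adjusted p 0.103) or wild-type replicate 1 (adjusted p 0.0938) and under quantile normalization (adjusted p 0.107). It was kept without dim genes (camera adjusted p 0.0480). Brighter genes leaned lower in general: the median difference was -0.025 over all genes left without dim genes, against -7.5e-04 over all genes tested. Under quantile normalization the medians of the proliferation and oxidative phosphorylation lists were -0.056 and -0.036. Decidual and parietal endoderm markers had medians of 0.53 and 0.21 in the same pools. In these 3 lists for growth and metabolism, 0 members passed when adjusted over the list alone. Genes of glycolysis and hypoxia (26 measured; median 0.011, camera adjusted p = 0.909) and cholesterol synthesis (18 measured, 0 called; 0 adjusted over the list alone; median -0.062, camera adjusted p = 0.203) did not pass, except the latter without mutant replicate 3 (median -0.094, adjusted p 0.0404), and its median was -0.0057 without mutant replicate 1. The hypoxia-induced gene Ndrg1 differed by -0.66 (SE 0.09, adjusted p = 0.0131), not without any 1 of the wild-type arrays (highest adjusted p 0.0919), and Pdk1, a kinase that inhibits pyruvate dehydrogenase, by -0.43 (adjusted p = 0.0953). Adjusted over the glycolysis and hypoxia list alone, 2 were lower. The mean of that list was 0.011 while camera placed it lower.

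Stress lists did not pass. The p53 target list (19 measured, 0 called) had a median of -0.023 (camera adjusted p = 0.855), the amino acid starvation and unfolded protein list (29 measured, 0 called) a median of -0.031 (camera adjusted p = 0.780), with asparagine synthetase, Asns, at -0.20. In both, 0 members passed when adjusted over the list alone. The immediate early and heat shock list (23 measured, 0 called; 2 higher adjusted over the list alone) had a median of 0.0091, from -0.018 to 0.035 with 1 array left out (camera adjusted p = 0.377), with the immediate early genes Jun at 0.58 (adjusted p = 0.0655) and Fos at 0.34 (adjusted p = 0.0575). Innate immune genes rose as a list, with a median of 0.11 over 19 measured, 1 called higher and 3 higher adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.317 with an estimated correlation). Its estimated correlation, 6.69e-04, lay below the preset 0.01, so correlation among its members does not account for that lost call. The 4 degrees of freedom of that setting raise p here too. With the preset, the list's call was lost without mutant replicate 3 (adjusted p 0.0563), and its median was 0.070 without wild-type replicate 2. Without dim genes the list passed with a median of 0.20 (camera adjusted p = 0.00315). Decidual and parietal endoderm markers had medians of 0.53 and 0.21 in the same pools. The RNA sensor Ddx58 was higher by 0.53 (SE 0.08, adjusted p = 0.0234), not without mutant replicates 1 or 2 or wild-type replicates 1 or 2 (highest adjusted p 0.144), and Irf9 differed by 0.27 (adjusted p = 0.129). Of 4 sex-linked genes measured, 0 were called and 0 passed when adjusted over the list alone (median 0.079, camera adjusted p = 0.680). Xist, the transcript of the inactive X chromosome, differed by 0.38 (SE 0.20, adjusted p = 0.525) and the Y-linked Uty by -0.32 (SE 0.33, adjusted p = 0.765), or by 0.099 and -0.050 without wild-type replicate 3, and Uty by -0.68 without mutant replicate 3.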

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

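All tests of this part except the splits of the arrays were chosen after the data were seen; for the decidual covariate, added then, the bound was set before its result was known. Among 13120 features that name no gene or several genes and stood outside the comparison of genes, 4 passed the limma threshold, all lower in the mutant and all listing several genes, with 0 among features without a gene. The 2 with the largest fall were feature_10405876, at -2.55 (adjusted p = 0.0232), and feature_10410248, at -1.62 (adjusted p = 0.0482). The real grouping of the 6 arrays gave 151 genes, was the only 1 of 10 splits to give as many, and the highest count of the other splits was 0. With 10 splits the share cannot fall under 0.05.

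The lower signal of trophoblast stem genes was set against the make-up of the pools. Fewer extraembryonic ectoderm cells in the mutant pools were considered as the whole cause. The prediction was that the list's members fall together by about the change of Bmp4, -1.11. The median of the 23 members was -0.23, with quartiles of -0.58 and -0.014, and Nr0b1 at -4.35 lay far below the rest. But Bmp4 is itself 1 of the 5 members called lower, so a median above its change was likely from that choice. The comparison therefore cannot decide. A loss of these cells, alone or beside a change within the cells, stays open. An effect of the Esrrb genotype on transcription in the tissue stays open as a hypothesis, untested beyond these arrays.

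The rise of decidual genes was set against maternal tissue in the pools. With 89.5% of the 19 listed genes higher in the mutant pools, and the most abundant, Prl8a2, at 11.46 against 10.71, the values that more maternal decidua would need were present, although Prl8a2 itself overlapped between groups (11.05 in mutant replicate 1, 11.25 in wild-type replicate 3) and Htra1 went the other way. The difference of Prl8a2, 0.75, ran from 0.49 without wild-type replicate 1 to 1.02 without wild-type replicate 3. Of the 19 genes, 3 stand in another list and 18 had wild-type signals above the median of all features. Other cells may therefore also express them. With a decidual score as a covariate, the median difference of the 70 genes called higher was 0.56 in place of 0.69, 80.9% of its size (quartiles over genes 65.7% and 107%), while the 81 lower genes kept 95.0%. The share set beforehand as speaking against decidual content as the whole cause, 75%, was passed but lay within that spread, a condition added after the value was seen. Genotype accounted for 72.5% of the variance of the score, the median standard error of the higher genes went from 0.10 to 0.16 and calls fell to 11, so how much of the rise goes with decidual content cannot be told apart from genotype.

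The rise of Afp and Trf was set against other tissues. The prediction for more visceral endoderm as the whole cause was that its other markers rise by about as much as Trf, 0.92. Apoa2 (1.22) and, chosen after their values were seen, Cer1 (1.24) and S100g (0.93) differed by as much, none past the threshold with all arrays. Of the 29 markers, 24 had a higher and 5 a lower mean in the mutant, and adjusted over the list alone 10 were higher and 1 lower. The median was 0.091 (quartiles 0.021 and 0.50). Without the called genes, Afp and Trf among them, it was 0.083 and the list still passed (camera adjusted p = 4.94e-04). The abundant Amn, also chosen after its value was seen, was at 10.38 in the mutant and 10.44 in wild type. Its difference was -0.064, from -0.12 to -0.024 with 1 array left out. Apoa4, brighter still at 11.76 against 11.26, differed by 0.50. Trf is itself 1 of the 2 markers called, so a median below its change was likely from that choice. The comparison therefore cannot decide. More visceral endoderm, or more of a part of it rich in these few genes, stays open. Apoa2 and S100g passed without mutant replicate 3 (adjusted p 1.82e-04 and 7.45e-04), where Cer1 differed by 0.78. Tissue from the embryonic side of the conceptus cannot be told apart, since the epiblast markers had a median of 0.16 and went both ways (quartiles -0.14 and 0.56), and that median ran from 0.028 without mutant replicate 3 to 0.31 without wild-type replicate 3. An effect of genotype on these genes stays open and untested.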

How the results depend on the processing

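The decidual covariate and the list tests without called genes were chosen after the data were seen. Esrrb kept its direction and call under all 15 alternatives run for it (-1.76 to -1.59). Of 52 named genes past the threshold, 27 stayed past it in all 14 fits fixed beforehand for single genes (13 for 5 dim genes), a minimum of 1 log2 unit not among them, and 25 lost the call when 1 array was left out. None of the 151 called genes changed sign in the fits run on 1 value per gene. The alternative for linear intensities was not run, since the table is on the log2 scale. Without detection calls, how far a low signal stands above background cannot be said.

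The 151 calls (81 lower, 70 higher) became 235 without dim genes (126 higher), because fewer genes were tested and the spread was estimated anew; for the other settings the cause was not tested. With a trend, 112 were higher; with array weights there were 380 (148 lower, 232 higher), mutant replicate 3 having the lowest weight, 0.467. An adjusted p under 0.1 gave 328 (143 lower, 185 higher), at least 1 log2 unit 34 (22 and 12), and the decidual covariate 11 (9 and 2), with Esrrb at an adjusted p of 0.0466. Quantile normalization gave 87 lower and 99 higher. With 1 array left out, counts ran from 47 to 265, lower genes from 32 to 127 and higher genes from 14 to 138; wild-type replicate 3 left out gave 53 lower. Of the 151 genes, 47, 46 and 140 were kept without wild-type replicate 1, wild-type replicate 2 and mutant replicate 3.

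With replicate number as a block, 361 genes passed (117 lower, 244 higher), 149 of the 151 among them, and 11 lists. The numbers were not shown to pair the pools: deviations of same-numbered pools correlated at 0.217, -0.068 and 0.315, and 2 of 3 mutant and 2 of 3 wild-type arrays correlated best with their own number. The decidual score rose with replicate number in both genotypes. It was 7.90, 7.95 and 8.17 in the mutant and 7.39, 7.52 and 7.76 in wild type. A batch shared by pools of the same number can be neither shown nor excluded. The block ended the call of the ectoplacental list (adjusted p 0.0650).

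Of 28 lists, 12 passed, 8 to 14 with 1 array left out, and 0 with an estimated correlation or by fry (18 by fry's mixed test). Over all alternatives, those just named included, list results held 48 that lost and 6 that gained a call and 17 that turned direction, the turns all of lists that had not passed, and the 1534 results of named genes held 134, 58 and 19, none of the last of a called gene. The cause of these turns was not tested. Given as medians, the direction that camera or fry gave turned for glycolysis and hypoxia under quantile normalization (0.016), without dim genes (0.010) and without called genes (0.012), for the amino acid starvation list under quantile normalization (0.0014) and without dim genes (-0.035), for p53 targets without dim genes and by fry (-0.023 in both), and for germ cell signals without called genes (-0.035). With 1 array left out, medians ran from -0.020 to 0.043 for glycolysis and hypoxia, -0.051 to 0.0036 for amino acid starvation, -0.049 to -0.0035 for p53 targets, -0.16 to 0.25 for sex-linked genes and -0.11 to 0.35 for giant cell genes. In the same way Ascl2 ran from -0.11 to 0.35, Esrra from -0.023 to 0.047, Esrrg from -0.13 to 0.037 and Tpbpa from -1.23 to 0.21. The decidual covariate turned Bmp2 (-0.15), Bmp8b (0.068), Ccnd1 (-0.29), Cer1 (-0.32), Esrrg (0.28), Fgf5 (-0.13), Kit (-0.074), Pou5f1 (-0.73), Prdm1 (-0.028), Tfap2c (0.16) and Prl8a2 (-0.55), which is part of the score.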

Other observations

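All tests of this part were chosen after the result was seen. Called genes lay next to each other on chromosomes. In the gene order of assembly GRCm38.p6, 5 pairs of neighbouring measured genes were called in the same direction, all lower in the mutant: Inpp1 and Hibch, Dppa4 and Dppa2, Duox2 and Duoxa2, Gm1673 and Nat8l, and Smad3 and Smad6. Hibch, Duox2, Duoxa2, Gm1673 and Smad3 were named after their values were seen, at -0.69, -0.92, -0.75, -1.01 and -0.51. Hibch encodes a valine breakdown enzyme, Duox2 and Duoxa2 an oxidase that makes hydrogen peroxide and its maturation factor, and Smad3 a mediator of Nodal and TGF-beta signals. Over 10000 random placements of the calls, the mean was 0.57 such pairs and the highest 5 (permutation p = 6.00e-04). Placement at random over all genes with a known place thus seldom gave as many pairs. Those placements took in bright and dim genes alike, so they do not test chance placement among expressed genes alone. Shared regulation of neighbours is a hypothesis that was not tested.

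X-linked genes made up 3.73% of the genes with a known place and 12.3% of those called lower, 10 of 81 (two-sided Fisher's exact p = 8.36e-04), and 5 of the 70 called higher (p = 0.189 by the same exact test). The 10 lower genes included Nr0b1, Wnk3, Nexmif and Radx. The median difference over all 742 X-linked genes was 0.0095, so the excess lay among individual genes. With fewer X chromosomes in the mutant pools, through more male embryos, Xist was predicted to fall. The bar for that fall was the median of these 10 genes, -1.04. Xist differed by 0.38 (95% interval -0.088 to 0.84), so it gave no sign of fewer female embryos in the mutant pools. But the bar comes from genes picked because they were lower, and it does not measure X dosage. The comparison therefore cannot decide whether the number of X chromosomes had a part in these calls. An effect of the Esrrb genotype stays open as a hypothesis, untested beyond these arrays.

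None of the 60 measured genes nearest to Esrrb was called by limma. At an unadjusted p under 0.05 there were 10 of 60, 16.7%, against 12.3% of all genes (one-sided Fisher's exact p = 0.197), and the median difference of the 60 was -0.010, too few genes to weigh DNA around the targeted locus either way.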
